A study of Mus musculus with 4 samples.

How the data were processed

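Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate Flag-tagged PGC-1alpha on the chromatin of C2C12 myotubes. Per the labels' protocols, cells at 90% confluence in 10% fetal bovine serum were switched to 2% horse serum for 72 h to form myotubes and were then cultured with an adenovirus encoding Flag-tagged PGC-1alpha. Crosslinked chromatin was precipitated with a monoclonal anti-Flag antibody on magnetic beads. The series has 4 samples, 2 immunoprecipitations and 2 whole cell extracts that served as the background. Nothing in the labels says whether the replicates came from separate cultures.

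Per the submitters' processing notes, Bowtie 0.12.7 and the mouse genome build mm9 were used. The peak caller, its thresholds and the way in which replicates were combined are not given in the sources used here. The authors deposited 1 peak list for the whole series, with 3 columns: chromosome, start and end. It was used as deposited, and its positions are given here 1-based on mm9. Each of the 7512 peaks is 200 bp wide, no pair of peaks overlaps, and the starts on each of the 21 chromosomes fall on a grid with a step of 25 bp. Positions are therefore given no finer than that step, and how accurately they locate binding is unknown. The list carries no height, fold enrichment or p-value for a peak, and no value for a replicate or an input. The sequencing depth behind a peak is unknown, and no interval for a peak and no comparison between replicates could be computed. All p-values below concern how the positions of 1 list are arranged and say nothing about the spread between cultures.

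These properties of the list were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. First, the peaks on each chromosome were compared with the chromosome's share of the summed spans by an exact two-sided binomial test, with Benjamini-Hochberg adjustment over 20 chromosomes and a threshold of 0.05. The span is the distance from the first to the last peak, because chromosome lengths of mm9 were not used here. Chromosome Y was left out of that test, since its peaks cover only a short stretch. Confidence intervals of densities are exact Poisson intervals at 95% and cover counting error only. Second, the share of peaks with a neighbour at a gap of at most 10 kb was compared with 1000 random placements of the peaks over the span of their own chromosome. The smallest two-sided p that these can give is 0.002. Finally, peaks were chained into regions wherever gaps were at most 10 kb. Numbers of pairs, regions, empty windows and long gaps expected by chance came from 200 further placements. Random placement did not avoid assembly gaps or sequence to which reads cannot be aligned uniquely.

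The regions named in the text follow a rule fixed before the data were examined for the case without an mm9 annotation: the 10 regions with the most peaks, ties going to the shorter region. The rule also asked for the widest peaks, which do not exist in a list of equal widths. Chromosomes, windows and gaps named beyond that rule were chosen after their values were seen. The alternatives planned before the data were examined were neighbour gaps of 2 and 50 kb, placement within occupied 1 Mb windows, moves of each peak by up to 500 kb, merging of touching peaks, and counting peaks within 10 kb once. Another 4 planned analyses need the mm9 sequence or gene positions on mm9 and were not run: position relative to genes, short sequence elements, gene lists, and the comparison of AP-1 with estrogen-related receptor elements. The gene table at hand describes GRCm38, another build, and its coordinates were not set against these peaks, so no gene is named.

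The computations were tested on simulated data. For the spacing test, these runs used fewer random placements per list than the 1000 used for the observed list. Among 20 simulated lists of 7485 randomly placed peaks, the spacing test called 2 at p under 0.05, so its false-call rate is only roughly known. It called all 20 lists into which 200 neighbouring pairs had been planted. The binomial test called 4 of 400 unchanged chromosomes, and called chromosome X in 20 of 20 simulations that gave it 50% of its share. These simulations drew peaks independently of each other. The search for evenly spaced runs, at least 4 peaks with steps within 25 bp of the first step, found 10 of 10 planted arrays. Those arrays had 9 peaks at exactly equal steps of 2300 bp and were kept clear of other peaks. Their recovery says nothing about less regular arrays.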

Results

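Candidate recruitment sites of Flag-tagged PGC-1alpha in muscle cells were mapped genome-wide by ChIP-seq. The antibody was directed against the tag, so sites of the cells' own PGC-1alpha were not mapped. PGC-1alpha is a transcriptional coactivator of mitochondrial and oxidative metabolism that reaches DNA through partner transcription factors. The study title names one such partner, AP-1, the dimeric factor formed by Fos and Jun proteins. C2C12 is a mouse myoblast line whose cells fuse into contractile myotubes. Myotubes expressing Flag-tagged PGC-1alpha from an adenovirus were profiled in 2 immunoprecipitations against 2 whole cell extracts, which are chromatin samples taken without antibody selection. The outcome examined here is a single list of peaks called against that background, on mm9. None of the 4 samples is an anti-Flag precipitation from cells without the tagged protein. A peak is therefore only a candidate recruitment site, because signal that such a precipitation would also give cannot be told apart. Read depth per library is unknown, and the list gives neither peak heights nor values per replicate, so the agreement of the 2 immunoprecipitations could not be measured.

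The immunoprecipitation against whole cell extract gave 7512 peaks on 21 chromosomes, which together covered 1502.4 kb. Chromosome 2 held 555 peaks and chromosome 1 held 551, the highest numbers of any chromosome. Chromosome X held 96, and chromosome Y held 27. The median gap between neighbouring peaks was 70.7 kb, with quartiles at 6.55 kb and 330.5 kb. The narrowest gap was 25 bp, which equals the step of the position grid, and the widest was 11.8 Mb.

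The first question was whether peaks were spread evenly over the chromosomes. They were sparse on chromosome X, where 0.608 peaks per Mb of span were found (95% Poisson interval 0.492 to 0.742), against 3.11 per Mb over the 19 autosomes together. The autosomes ranged from 2.26 per Mb on chromosome 18 to 4.45 per Mb on chromosome 19, with a mean of 3.17 ± 0.602 per Mb (SD over 19 autosomes). Chromosome X thus carried 0.206 times the number of peaks expected from its span, 96 against 467 (exact binomial test, two-sided, adjusted p = 1.07e-99). The shortage ran along the whole chromosome: each of its 16 windows of about 10 Mb fell below the autosomal median of 27.7 peaks per 10 Mb, and the fullest held 16.2 per 10 Mb.

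**Figure D1:**
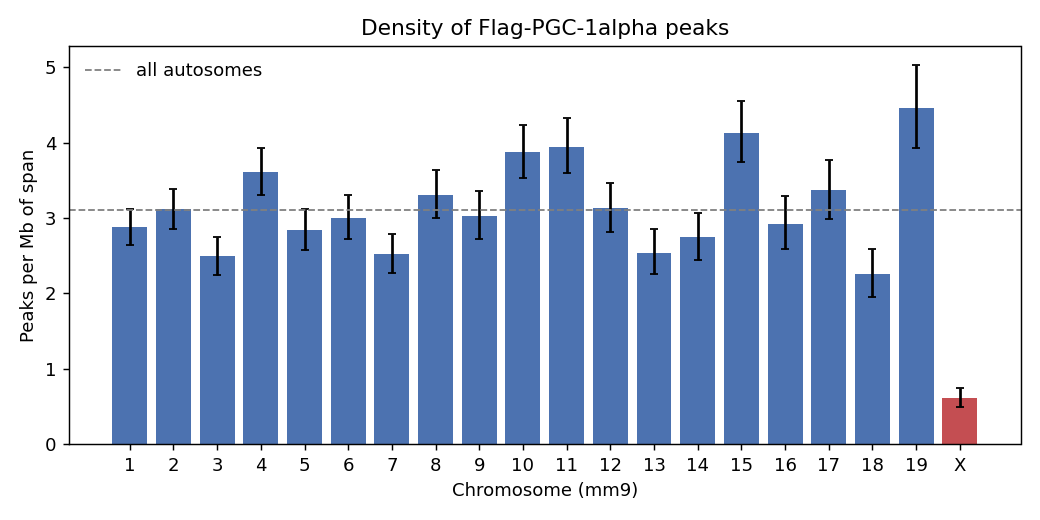
Peaks per Mb of span (vertical axis) for each chromosome on mm9 (horizontal axis). Bars are densities, error bars are exact 95% Poisson intervals that cover counting error only, and the dashed line is the density of all autosomes together, 3.11 per Mb. Chromosome X stands at 0.608 per Mb, below each autosome.

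Among the autosomes, chromosomes 19, 15, 11, 10 and 4 held the most peaks for their span. Chromosome 19 held 1.51 times its expected number (258 peaks, exact binomial test, adjusted p = 2.79e-09) and chromosome 15 held 1.40 times (413 peaks, adjusted p = 4.02e-10). The corresponding ratios were 1.34 for chromosome 11, 1.31 for chromosome 10 and 1.22 for chromosome 4. Chromosomes 18, 3, 7 and 13 held fewer than expected, with ratios of 0.763, 0.843, 0.853 and 0.860. These expected numbers include the sparse chromosome X, which raises the ratio of each autosome. With autosomes only, the ratio was 1.43 for chromosome 19, 1.33 for chromosome 15 and 0.725 for chromosome 18. All 9 autosomes named so far in this paragraph kept their call in that setting. With peaks within 10 kb counted once, chromosomes 3, 7 and 13 lost their call, at ratios of 0.910, 0.885 and 0.927 (exact binomial test, adjusted p = 0.163, 0.0765 and 0.324), and chromosome 18 kept it at 0.813. In all, 7 chromosomes lay above and 5 below their share of span by the exact binomial test, chromosome X among the latter. That test treats peaks as independent. A permutation test that compared windows of about 10 Mb on one chromosome with those on all others, added after the data were seen, called 0 chromosomes above and 1 below; this was chromosome X (100000 resamples, adjusted p = 4.00e-04).

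Chromosome 8 lay at 1.12 times its expected number (422 peaks, exact binomial test, adjusted p = 0.0366) and chromosome 17 at 1.14 times (293 peaks, exact binomial test, adjusted p = 0.0439). Neither was called when chromosome X was left out of the expected shares, with ratios of 1.06 for chromosome 8 (exact binomial test, adjusted p = 0.280) and 1.08 for chromosome 17 (exact binomial test, adjusted p = 0.253). Chromosome 8 also lost its call when peaks within 10 kb were counted once (ratio 1.09, exact binomial test, adjusted p = 0.206). Its peaks were gathered at the distal end. The window from 121060094 to 130882805 held 152 of them, which is 36.0% of the peaks of the chromosome in 7.69% of its span. This was the densest of the windows of about 10 Mb into which the spans were divided, at 5.58 times the autosomal median. On the other chromosomes the densest window held at most 32.2% of the peaks, on chromosome 19. That chromosome was divided into only 6 such windows, against 13 on chromosome 8, so each window is a larger part of its span.

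**Figure D2:**
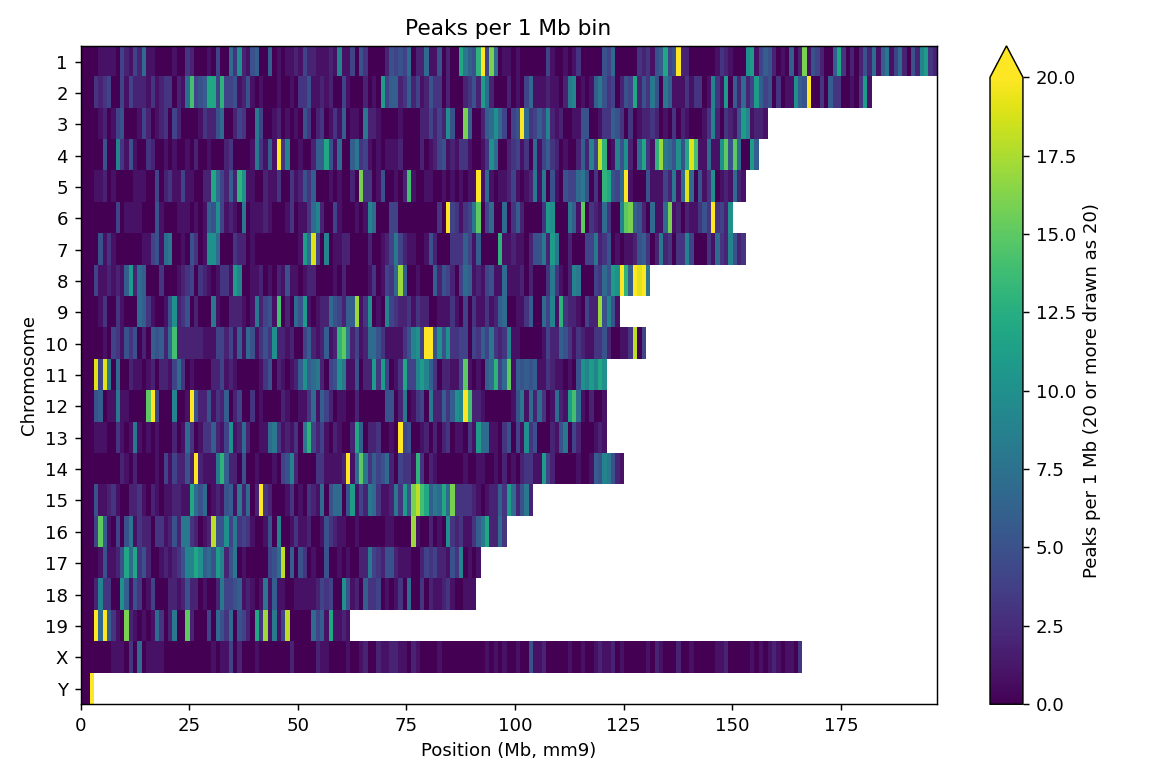
Number of peaks in each 1 Mb bin (colour, bins with 20 or more drawn as 20) by position in Mb on mm9 (horizontal axis) and chromosome (vertical axis, each row ending at its last peak). Dense bins alternate with long empty stretches on the autosomes, the distal end of chromosome 8 is filled, chromosome X is sparse throughout, and the 27 peaks of chromosome Y lie in a short stretch.

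Within chromosomes, peaks were concentrated in a minority of the sequence. Of 2520 windows of 1 Mb outside chromosome Y, 783 (31.1%) held no peak, compared with a mean of 8.02% and a highest value of 9.25% in 200 random placements. The fullest 334 windows, 13.3% of the total, contained 50% of the peaks, whereas random placement needed at least 27.1% of windows. With windows laid from the first peak of each chromosome, the fullest was on chromosome 8 from 124187556 to 125187555 and held 38 peaks, where the highest random window held 15. Other full windows lay on chromosome 14 from 25481773 to 26481772 with 34 peaks, on chromosome 12 from 25256295 to 26256294 with 30, and on chromosome 10 from 79957128 to 80957127 with 29. Their order depends on where windows begin: in bins laid from position 0, as drawn in the map of peaks per bin, the bin of chromosome 14 that begins at 26 Mb led with 33 peaks, and that of chromosome 8 at 124 Mb held 29.

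Long stretches without a peak were also found. The longest lay on chromosome 7 from 39057073 to 50880147 (11.8 Mb) and on chromosome X from 18740222 to 30546996 (11.8 Mb). A stretch on chromosome 6 from 72333699 to 82701948 measured 10.4 Mb. On the autosomes, 29 stretches exceeded 4.80 Mb, the longest gap that 200 random placements gave there. Of the 10 longest stretches in the genome, 4 were on chromosome X, where peaks are sparse and random placement also gave long gaps. The longest gap on chromosome X was at least as long as the observed one in 12 of 200 placements, with a mean of 8.60 Mb. Assembly gaps and repeats that reads cannot be assigned to were not taken into account.

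The second question was whether peaks lay in groups. They did: 3293 of the 7512 peaks (43.8%) had another peak within 10 kb, against a mean of 6.56% and a highest value of 7.69% in 1000 random placements, an excess of 6.68 times (permutation test, two-sided, p = 0.002, the smallest that these placements can give). Within 2 kb, 26.1% of peaks had a neighbour, 15.6 times the random mean, and within 50 kb 64.1% had one, 2.35 times the random mean, with the same p in each case. Moving each peak at random by up to 500 kb keeps density over megabase regions but not over shorter distances. After such moves, 13.9% on average still had a neighbour within 10 kb. The observed share was 3.16 times that value (permutation test, p = 0.002).

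The excess was greatest at short distances and declined steadily. Outside chromosome Y, 560 pairs of peaks had starts 0.2 to 1 kb apart, 29.3 times the mean of 200 random placements. The ratio was 27.7 for pairs 1 to 2 kb apart, 8.71 for pairs 5 to 10 kb apart, 3.13 for pairs 50 to 100 kb apart and 1.48 for pairs 500 to 1000 kb apart. It was still 1.14 between 2000 and 5000 kb. In each of these distance bands the observed number exceeded the highest random number.

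**Figure D3:**
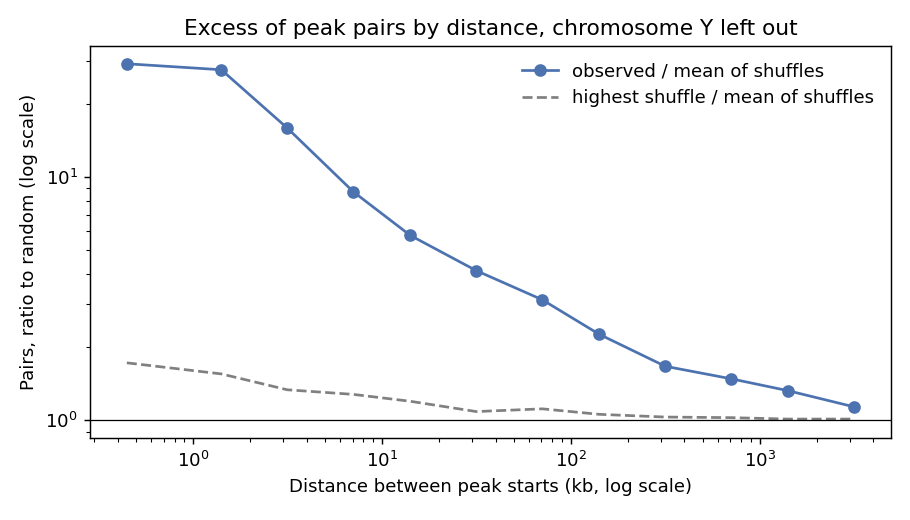
Number of pairs of peaks, as a ratio to the mean of 200 random placements (vertical axis, log scale), by the distance between their starts in kb (horizontal axis, log scale), without chromosome Y. Points are the observed ratios, drawn at the geometric middle of each distance band, and the dashed line is the highest random placement; the ratio falls from 29.3 below 1 kb to 1.14 between 2000 and 5000 kb.

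Chaining peaks across gaps of at most 10 kb gave 5405 regions. Of these, 4219 held a single peak, and 1186 held more than 1 and had a median length of 3.78 kb. There were 739 regions of 2 peaks, 252 of 3, 96 of 4 and 99 of 5 or more, and the last group contained 675 peaks. Outside chromosome Y, random placement gave on average 223.3 regions of 2 peaks and 6.91 of 3. The largest random region had 5 peaks, and 98 observed regions had 5 or more.

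The region with the most peaks lay on chromosome Y from 2701790 to 2761289 and held 26 peaks in 59.5 kb. Chromosome 14 had the next, with 17 peaks in 33.7 kb from 61548773 to 61582472, and a further one with 11 peaks in 29.2 kb from 26324873 to 26354047. Regions of 15 peaks lay on chromosome 12 from 88138845 to 88177869 (39.0 kb) and on chromosome 13 from 73819593 to 73872092 (52.5 kb). Chromosome 8 had 12 peaks in 18.1 kb from 124658131 to 124676230, inside its fullest 1 Mb window. Chromosome 1 had 11 peaks in 24.2 kb from 92131176 to 92155350, and chromosome 19 had 10 peaks in 17.4 kb from 5832062 to 5849461. Of the 6 regions with 9 peaks, the shortest were on chromosome 2 from 167198779 to 167209453 (10.7 kb) and on chromosome 15 from 41699210 to 41713359 (14.2 kb). The region on chromosome 2 was the most compact of the 10, with 16.9% of its length inside peaks. The genes at these positions were not analysed here.

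**Figure D4:**
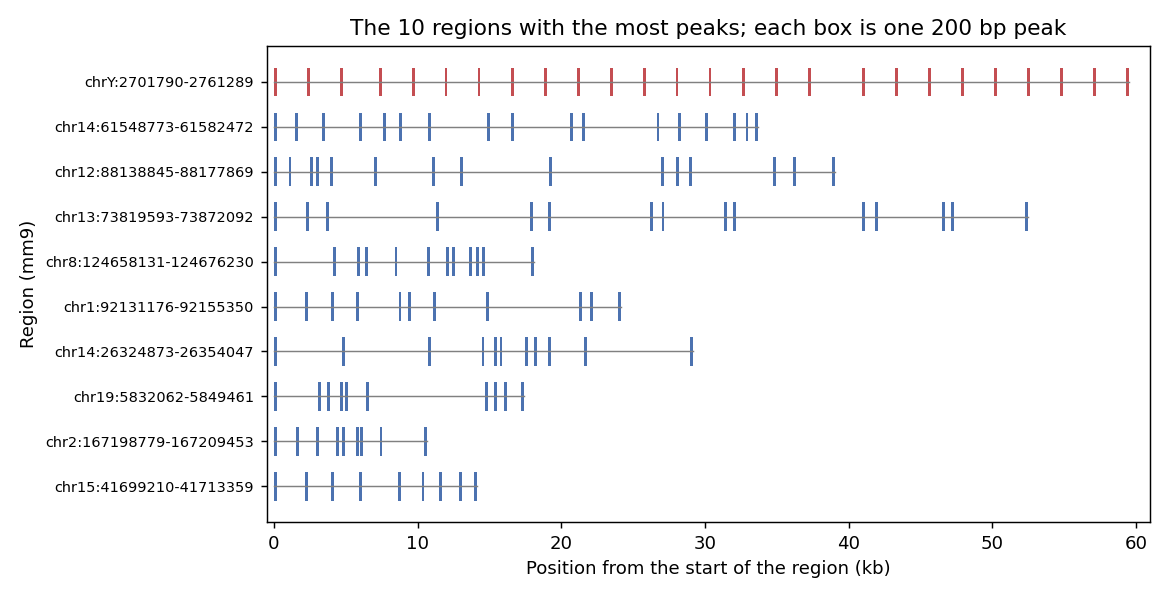
Positions of the 200 bp peaks (boxes) within the 10 regions with the most peaks, in kb from the start of each region (horizontal axis), with the mm9 coordinates of each region on the vertical axis. Peaks on chromosome Y (red) stand at near-equal steps; the spacing in the other regions (blue) is irregular.

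The peaks of chromosome Y differed from those elsewhere in their spacing. All 27 lay between 2691240 and 2761289, a stretch of 70.05 kb. Of the 26 intervals between their starts, 23 were within 25 bp of 2300 bp, compared with at most 4 within 25 bp of their own median in 1000 random placements in the same stretch. On the other chromosomes, 17 of 7465 intervals (0.228%) lay within 25 bp of 2300 bp. A search for runs of at least 4 evenly spaced peaks returned 2 runs in the genome, of 14 and 9 peaks, both in this stretch. Leaving out chromosome Y gave 7485 peaks and left the share of peaks with a neighbour within 10 kb at 43.7%.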

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

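The settings that leave out chromosome Y, chromosome X, the densest window of a chromosome or evenly spaced runs, count peaks within 2 kb as 1 site, or permute windows were added after the data were seen. The excess of close neighbours kept its direction and its side of the threshold in all 7 alternatives, with ratios from 2.35 (gap of 50 kb) to 15.6 (gap of 2 kb). The shortage on chromosome X also held, at 0.252 times the expected number with peaks within 10 kb counted once and 0.206 by permuting windows. Counts of chromosomes did not hold: those above their share fell from 7 to 0 when windows were permuted, and those below fell from 5 to 2 with close peaks counted once and to 1 with windows permuted. With autosomes only, 5 lay above and 5 below: chromosomes 8 and 17 lost their call and chromosome 14 gained one (0.882, exact binomial test, adjusted p = 0.0405). Counting close peaks once left fewer items to test, and 4 of the 11 called autosomes (3, 7, 8 and 13) lost their call and 7 kept it. The window permutation, which lets peaks in a window vary together, kept 0 of 11, but only the p-values moved: the ratios, such as 1.51 for chromosome 19 and 0.763 for chromosome 18, are nearly the same quantity in both tests. Leaving out the densest window of a chromosome lowers its ratio by construction and is no test; it did so on all 20, and took chromosome 8 to 0.788 and chromosome 17 to 0.946, while the other 5 called above their share stayed above 1. Merging touching peaks left 7512. A stricter list could not be formed, because all widths are equal and no score is given. Not run for want of the mm9 sequence or annotation were all alternatives on gene position, sequence elements, gene lists and AP-1 against estrogen-related receptor elements. No paired analysis was possible because the list holds no values per replicate; for the same reason no replicate could be left out. Depth is unknown, so no limit on undetected sites can be given.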

Other observations

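Chromosome 8 had the highest share of peaks in the distal 50% of its span, 72.5%, and chromosome 17 the lowest, 32.4%. Apart from the distal end of chromosome 8, the fullest windows of about 10 Mb lay on chromosome 15 from 73193880 to 83191314 (100 peaks), chromosome 1 from 85571632 to 95655185 (99 peaks), chromosome 10 from 78240528 to 88566727 (99 peaks) and chromosome 19 from 3085612 to 12740723 (83 peaks), between 3.10 and 3.61 times the autosomal median. On chromosome X, 16.7% of peaks had a neighbour within 10 kb, against 43.8% in the whole list; the difference was not tested, and lower density alone lowers this share.

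Of the tests that follow, only the moves of up to 500 kb were planned before the list was opened. The contrast between immunoprecipitation and whole cell extract gives no group within the list, so no explanation from the study's groups was tested. Of biological explanations, only an assumed copy number of chromosome X was.

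Peaks lay closer together than random placement allows. If broad regions split at gaps of up to 2 kb gave the whole excess, counting such peaks as 1 site should have removed it. Of the 6372 sites, 25.8% still had another within 10 kb, against at most 6.69% by chance. The excess over the random mean fell from 6.68 to 4.56 times. Broad regions split at wider gaps are not merged by this count, so such splitting stays open. Uneven density over megabase regions alone would leave the share within the range given by moving each peak by up to 500 kb, and 43.8% lay above the highest of these, 15.4%. Without the evenly spaced arrays the share was 43.7%, against at most 7.52% by chance. Density that varies over shorter distances, such as that of open chromatin or of sequence that reads can be assigned to, stays open and was not tested.

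Chromosome X held few peaks. A local gap in part of the chromosome would leave other windows at the autosomal level, but 100% of its 16 windows lay below the autosomal median. With an assumed 1 copy of X against 2 of each autosome and peak numbers in proportion to copies, the density ratio should reach 0.5. The observed ratio was 0.195, with a 95% bootstrap interval over windows of 0.131 to 0.266. Copy numbers of the chromosomes in these cells were not measured, so only that assumed proportion was tested. Fewer copies could still contribute if a peak caller's threshold removes more than a proportional share, which needs read depth to test, and fewer genes or more repeats on this chromosome also remain open, since the mm9 annotation and sequence were not used here.

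A candidate explanation for the evenly spaced peaks on chromosome Y is copies of one tandem repeat in the reference, each giving a peak of its own: 23 of 26 intervals lay within 25 bp of their median of 2300 bp, where random placement gave at most 4. The test was built on the pattern it describes, and a match to repeat sequence was not examined. Whether these peaks reflect PGC-1alpha or a surplus of reads over whole cell extract at repeated sequence stays open. Without chromosome Y the excess of close neighbours was 6.99 times the random mean, against 6.68 with it.

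A shared gradient along the chromosomes was tested as a hypothesis, that peaks are denser toward the distal end of autosomes. The distal 50% of the span held a mean of 55.1% ± 11.7 of the peaks (SD over 19 autosomes), above 50% on 14 of 19. A sign-flip permutation test over autosomes gave p = 0.0775 (two-sided, 100000 resamples), so a gradient common to the autosomes was not shown.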
